A study of Oryza sativa with 2 samples.

How the data were processed

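Intermediate-size non-coding RNA was sequenced from rice (Oryza sativa) in 2 libraries, 1 for each of 2 developmental stages. Per the labels' protocols, total RNA was fractionated to keep molecules of 50 to 500 nt, adaptors were ligated to both ends of the RNA, with a 5′ adaptor specific for the structure of that end, and reverse transcribed cDNA that had not been amplified went to 454 pyrosequencing.

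The authors deposited 1 position list per library, with 6 columns and no header: chromosome, start, end, locus name, a whole number and strand. The whole number in column 5 was read as the count of reads per locus, not normalized. That reading rests on the values, since the smallest was 1, the totals differed between the libraries, and the same locus name carried different numbers in each. The aligner, the genome build, the rule that defined a locus and the treatment of reads with several matching positions are not given in the sources used here. Both lists drew on a single series of locus names that ran from 1 to 1349 with no number missing, and a locus in both lists had the same position in each. The lowest sum of reads over both libraries was 2 for any locus. A locus missing from a list was taken to have 0 reads there. Chromosome names are those of the files, where chrC and chrM are the names rice assemblies use for the chloroplast and mitochondrial genomes. Start positions were raised by 1 on the assumption that the lists follow the BED convention, and lengths are end minus start as deposited. If the authors counted from 1 instead, starts are too high by 1 and lengths too short by 1.

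Reads per 1e6 library reads (RPM) were computed from the sum of counts in each list. The stage 2 to stage 1 ratio of RPM was given an exact conditional binomial 95% interval. With 1 library per stage there is no replicate error, and count models that need replicates could not be fitted. Intervals and floors cover counting error only, treat reads as independent molecules, and are too narrow where a read was counted at several loci. Every test compares these 2 libraries or lists, not the stages. A locus with 0 reads in 1 library was compared with a floor of 3 reads in that library. The value is called a bound here, and it leaves out the counting error of the other library's count. The floor corresponds to 37.2 RPM in stage 1 and 25.5 in stage 2. Ratios were summarised for loci with at least 20 reads over both libraries, with 2-fold as a rule of size. Log2 ratios were computed after adding 0.5 reads to each count.

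Distinct loci were sets of intervals overlapping by at least 1 nt on the same strand of 1 list. Loci were shared where each covered at least 0.5 of the other's length on the same strand. Random placement as a measure of chance sharing is not reported, because both lists drew on 1 set of intervals and its outcome was fixed by that. Clusters were loci at most 500 nt apart on the same strand, compared with 1000 random placements. Placements ran from the start of each chromosome to the highest end listed on it. Shares were given exact Clopper-Pearson intervals and compared by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over 3 classes (nuclear, chloroplast, mitochondrial). Median lengths were compared by a two-sided permutation test with 100000 resamples, and chromosome distributions by 10000 Monte Carlo tables. Loci shared by both lists enter both sides of these tests, so the entries are not independent.

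The loci named were fixed before the data were examined as the 10 with most reads in each library and the 5 with the highest and 5 with the lowest ratio among loci of at least 20 reads; a locus with 0 stage 1 reads ranked first, and such loci were ordered by stage 2 reads. Other loci named, and the set of loci as long as the most abundant stage 1 locus, were chosen after their values were seen. Nuclear loci were said to repeat organelle loci where they had equal length and equal counts in both libraries and lay in runs of at least 2 loci whose offsets to the organelle positions differed by at most 1000 nt from 1 to the next. The planned classes by RNA type and by host gene were not run, since no annotation of the authors' build was used here, and for the same reason no locus is placed in a gene, exon or intron. The planned total without rRNA and tRNA loci was not run either. A RefSeq gene table of assembly ASM3414082v1 was used only for the lengths and chromosomes of snRNA genes in the closing section.

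The interval method was checked on simulated counts for the real loci. Of 50 loci simulated at 2-fold higher in stage 2, 88.0% had an interval that excluded 1, as did 78.3% of 46 simulated at 0.5-fold, so changes of that size can be missed. Of 279 unchanged loci, 5.0% did. The simulation drew independent Poisson counts, as the interval assumes, so a rate near this was set in advance. It does not give the error rate between real libraries. Alternatives covered the merging and overlap rules, strand, the 50 to 500 nt range, the read minimum, the denominators and the cluster distance. Scaling to the median locus (dividing each ratio by the median ratio of the loci with at least 20 reads), entering loci of equal length and counts once, leaving out named sets, and removing nuclear loci that repeat organelle loci were added after the data were seen. So was clustering of only the loci with at least 20 reads. Analyses used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1.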

Results

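The series surveyed non-coding RNAs of 50 to 500 nt at 2 stages of rice development. Stage 1 is labelled with coleoptile, tissue given as radicals, shoot and leaves at tillering, and stage 2 with anther, pistil and embryo; whether the tissues were pooled before RNA extraction is not stated. The stage 1 list held 838 loci with 80651 reads, and the stage 2 list held 1163 loci with 117798 reads. Each stage had 1 library, so no value has a replicate error and each comparison below is between 2 libraries. Loci carry the authors' names (JNnc_loci followed by a number), and positions are those of the files, whose genome build is not given in the sources used here.

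Reads were concentrated in few loci, and more so in stage 1. The 10 loci with most reads took 26.5% of stage 1 reads (95% Clopper-Pearson interval 26.2 to 26.8) and 15.9% of stage 2 reads (15.7 to 16.1). At the other end, 34.8% of the stage 1 loci and 42.6% of the stage 2 loci had 3 reads or fewer. The median was 12 reads per locus in stage 1 and 6 in stage 2.

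The first comparison asked which loci were found at both stages. Of 1349 loci, 652 were listed in both libraries, 186 in stage 1 only and 511 in stage 2 only. The shared loci were 77.8% of the stage 1 list and 56.1% of the stage 2 list. They held 99.3% of stage 1 reads and 98.2% of stage 2 reads. Both lists use 1 common set of intervals, so the overlap rule had no bearing on the number. Loci of a single list were weakly covered, with a median of 3 reads in each. Of these, 158 in stage 1 and 394 in stage 2 had 2 or 3 reads. No stage 1 locus missing from stage 2 exceeded 9 reads, while 26 stage 2 loci missing from stage 1 had 10 or more and 7 had 20 or more. The 26 include JNnc_loci1300 on chrC, 45 nt long with 17 reads. They also include JNnc_loci0113, JNnc_loci0485, JNnc_loci1085, JNnc_loci1135 and JNnc_loci1225, nuclear loci that have its length and counts and may repeat it. Thinning stage 2 to the stage 1 total, and keeping loci with at least 2 reads over both libraries as in the lists, left 995 ± 9.98 loci (mean and SD of 1000 draws) beside the 838 of stage 1. The stage 1 list was not filtered again after thinning, though 79 of its loci have 1 read and meet the minimum only through stage 2 reads. The rule that listed a locus is not known beyond that minimum, so these numbers need not be on a common footing.

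Loci with 20 or more reads in stage 2 and 0 in stage 1 numbered 7, and 4 of them lay on the plus strand of chromosome 4. JNnc_loci0542 (chromosome 4, 21065482 to 21065591) had 217 reads in stage 2 and 0 in stage 1, 49.5-fold higher against a floor of 3 reads (interval from 39.9). JNnc_loci0543 lay beside JNnc_loci0542 at 21067817 to 21067984 and had 23 reads against 0, 5.25-fold higher against the floor (interval from 3.94). JNnc_loci0545 (21366084 to 21366230) and JNnc_loci0546 (21367178 to 21367291) had 27 and 22 reads against 0. They were 6.16-fold and 5.02-fold higher against the floor (intervals from 4.68 and 3.75). JNnc_loci1105 on chromosome 10 (12722626 to 12722711) had 35 reads against 0, 7.99-fold higher against the floor (interval from 6.16). The other 2, JNnc_loci0263 and JNnc_loci0049 on chromosomes 2 and 1, had 21 and 20 reads. JNnc_loci0544 and JNnc_loci0547, neighbours on chromosome 4, had 2 reads each in stage 2 and 0 in stage 1. These bounds do not rank the loci: JNnc_loci0972 on chromosome 8, with 1 and 97 reads, had a ratio of 66.4 (11.6 to 2650) and JNnc_loci0148 on chromosome 1, with 2 and 102 reads, 34.9 (9.42 to 292). The last 6 loci were chosen after their values were seen.

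The most abundant loci in stage 1 were mainly of a single length, 196 nt. Of its 10 strongest loci, 6 had that length: JNnc_loci0175, JNnc_loci0182, JNnc_loci0913, JNnc_loci0917, JNnc_loci0176 and JNnc_loci0894, with 2875, 2712, 2686, 2205, 1611 and 1284 reads. The 13 loci of 196 nt in the lists lay on chromosomes 2, 7, 8 and 12. Together they took 18.9% of stage 1 reads (18.7 to 19.2) and 6.25% of stage 2 reads (6.11 to 6.39), a stage 2 to stage 1 ratio of 0.330 (95% interval 0.321 to 0.339). The ratio was under 1 in 12 of the 13, each with an interval below 1. JNnc_loci0248 was the exception at 1.41 (0.781 to 2.63), on 18 and 37 reads. The loci differed from one another: JNnc_loci0917 (chromosome 7, 29111841 to 29112036) was lowest at 0.0559 (0.0477 to 0.0651), from 27340 to 1528 RPM. JNnc_loci0277, JNnc_loci0182 and JNnc_loci0913 were at 0.151, 0.152 and 0.206, and the other 9 lay between 0.447 and 1.41. Without the 6 strongest the set was at 0.465 (0.433 to 0.499). Scaled to the median locus, the whole set was at 0.238 and JNnc_loci0248 at 1.01. This set by length was chosen after the values were seen.

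**Figure D1:**
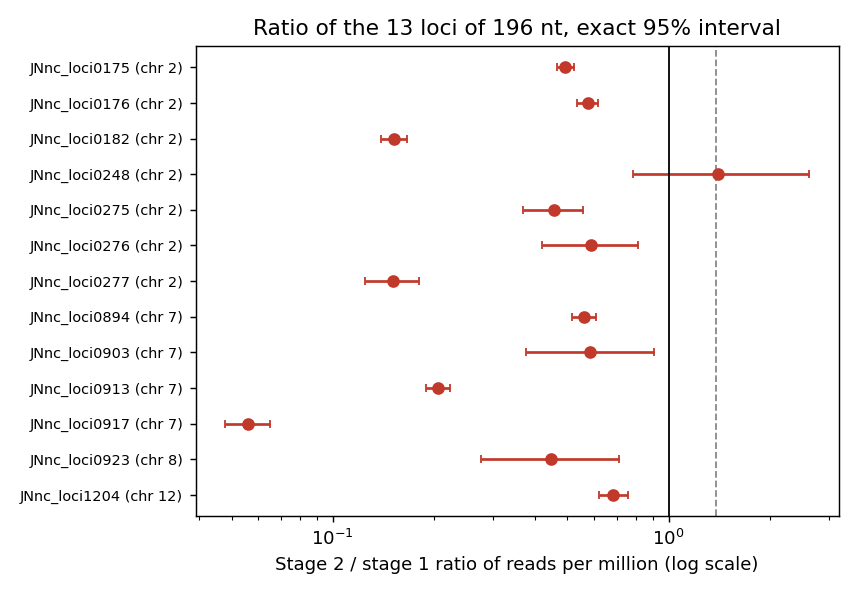
Stage 2 to stage 1 ratio of RPM (log axis) for the 13 loci of 196 nt; points are ratios, bars exact 95% intervals for counting error, the solid line is 1 and the dashed line the median ratio of 1.39 over 483 loci. JNnc_loci0917 sits lowest at 0.0559 and JNnc_loci0248 alone reaches above 1.

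Other strong loci differed in their balance between libraries. JNnc_loci0800 (129 nt, chromosome 6) and JNnc_loci0735 (154 nt, chromosome 6) were lower in stage 2, with ratios of 0.466 (0.439 to 0.495) and 0.451 (0.419 to 0.485). JNnc_loci1141 (161 nt, chromosome 10) was at 0.789 (0.734 to 0.849). JNnc_loci0909 (125 nt, chromosome 7), the strongest locus of stage 2 with 3002 reads, had a ratio of 0.977 (0.924 to 1.03), or 0.704 when scaled to the median locus. JNnc_loci0818 (83 nt, chromosome 6) was 4.23-fold higher in stage 2 (3.72 to 4.82) and JNnc_loci0986 (89 nt, chromosome 8) 2.28-fold higher (2.10 to 2.48). The last 4 of the 10 strongest stage 2 loci, JNnc_loci0359, JNnc_loci1184, JNnc_loci1185 and JNnc_loci1239, are 101 nt long and lie on chromosomes 3, 11 and 12. Each had exactly 854 and 1531 reads, and their ratio of 1.23 turned to 0.884 when libraries were scaled to the median locus.

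Over the 483 loci with at least 20 reads, 159 were at least 2-fold higher in stage 2 and 56 at least 2-fold lower. The median log2 ratio was 0.47, a ratio of 1.39. Scaled to that median, 88 were at least 2-fold higher and 107 at least 2-fold lower, so the split between directions depends on the scaling. Intervals for counting error lay above 1 for 234 loci and below 1 for 110. Counts of the 652 shared loci correlated across loci between the libraries (Pearson r of log2 counts 0.89, Spearman rho 0.90); loci are not independent replicates. The 5 lowest ratios were those of JNnc_loci0917, JNnc_loci0404 at 0.0786 (0.0303 to 0.172), JNnc_loci0318 at 0.0947 (0.0645 to 0.135), JNnc_loci0793 at 0.123 (0.0786 to 0.187) and JNnc_loci1251 at 0.144 (0.0357 to 0.434). JNnc_loci1251, on chromosome 12, rests on 19 and 4 reads and has the length and counts of a locus on chrM.

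**Figure D2:**
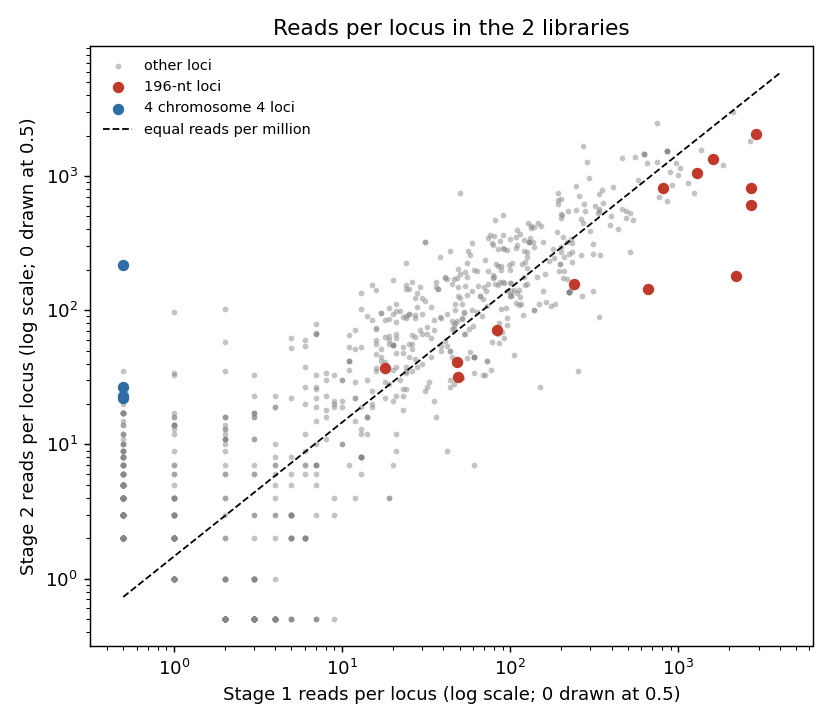
Reads per locus in stage 1 and stage 2 (both axes log, 0 drawn at 0.5); red points are the 13 loci of 196 nt, blue points the 4 chromosome 4 loci, and the dashed line marks equal RPM. JNnc_loci0542 has 217 stage 2 reads and 0 stage 1 reads, and 12 of the 13 red points lie below the line.

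Lengths of the listed loci were set beside the size fraction. Both lists use 1 common set of intervals, so lengths differ between them only through which loci are listed. The median distinct locus was 100 nt in stage 1 (quartiles 82 and 140) and 87 nt in stage 2 (70 and 131), 13 nt shorter in stage 2. A two-sided permutation test over 837 and 1162 distinct loci gave p = 1e-05, the smallest that 100000 resamples can give. Only 3 stage 1 and 14 stage 2 loci were under 50 nt, and 4 in each list were over 500 nt. The 14 include JNnc_loci1300 on chrC, of 45 nt, and the nuclear loci with its length and counts. Stage 2 loci missing from stage 1 had a median of 69 nt, stage 1 loci missing from stage 2 87 nt, and loci in both 106 nt. Loci under 70 nt made up 261 of the 511 found in stage 2 only, while all loci of that size held 1.31% of stage 2 reads. By reads, loci of 150 to 199 nt took 34.8% of stage 1 and 21.3% of stage 2, and loci of 70 to 99 nt took 27.4% and 37.0%. Without the 13 loci of 196 nt the longer class took 15.8% and 15.0%, and its ratio went from 0.612 to 0.949 (0.928 to 0.971), or from 0.441 to 0.684 when scaled to the median locus. The ratio of the shorter class, 1.35, became 0.971 under that scaling.

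**Figure D3:**
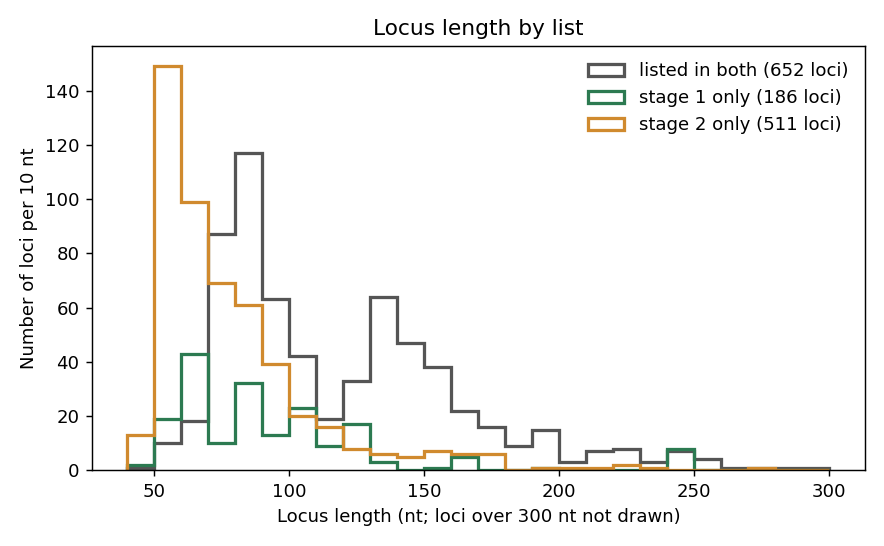
Number of loci per 10 nt of length for loci listed in both libraries (grey, 652), stage 1 only (green, 186) and stage 2 only (orange, 511); 15 loci over 300 nt are not drawn. Loci in both lists show a peak of 117 loci at 80 to 89 nt and another of 64 at 130 to 139 nt.

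Organelle loci were compared as the classes that chromosome names allow. The chloroplast chromosome held 27 stage 1 loci (3.23%, 2.14 to 4.66) and 20 stage 2 loci (1.72%, 1.05 to 2.65), a difference that did not pass after adjustment (Fisher's exact test over the 2 lists, raw p = 0.0355, adjusted p = 0.106). Its reads were few, 92 and 72, with a ratio of 0.536 (0.388 to 0.737). The mitochondrial chromosome held 23 and 28 loci (2.75% and 2.41%, exact test adjusted p = 0.668) with 1247 and 1014 reads, a ratio of 0.557 (0.512 to 0.605). Of these, 1120 and 685 reads were the 224 and 137 reads of 5 loci of equal length. With such groups entered once the ratio was 0.854 (0.739 to 0.988), and without these 5 loci it turned to 1.77 (1.44 to 2.19), on 127 and 329 reads. Nuclear loci made up 94.0% and 95.9% of the lists (exact test adjusted p = 0.111). The distribution over the 14 chromosomes did not differ detectably between the lists (Monte Carlo permutation p = 0.803), nor did the strands (p = 0.476). These tests hold the shared loci on both sides. Among loci of a single list, a test chosen after the data were seen did differ (Monte Carlo permutation p = 0.0008): chrC held 16 of the 186 stage 1 only loci (8.60%) and 9 of the 511 stage 2 only loci (1.76%). Without chrC that difference did not pass (Monte Carlo permutation p = 0.123). Chromosome 3 held the most loci, 184 of 1349.

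Part of the nuclear list repeated organelle loci. On chromosome 10, 26 of the 30 loci between 10729105 and 10844973 had the length and both counts of a chrC locus. They formed separate runs: 21 loci from 10736226 to 10823424 kept the order and strand of chrC loci from 212 to 87506, with offsets within 98 nt of one another. The 3 loci before them matched a mirrored pair of chrC segments, and the last 3 (the first of which also ends the long run) lay in the opposite orientation. Across 9 nuclear chromosomes 120 loci fell in such runs, against at most 6 when counts were shuffled among nuclear loci 100 times. They comprised 49 of the 186 stage 1 only loci and 30 of the 511 stage 2 only loci. Without them the libraries shared 611 loci.

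**Figure D4:**
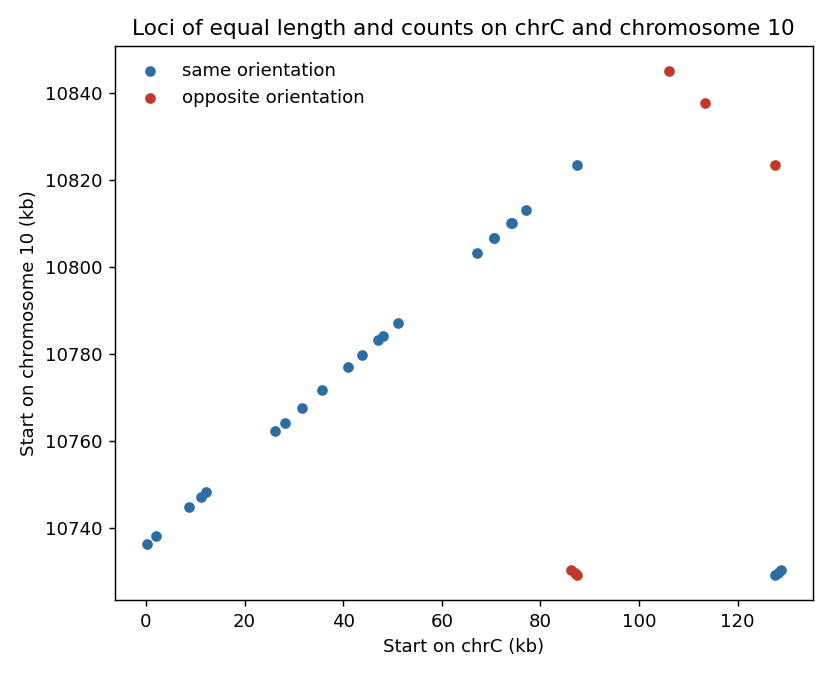
Start positions in kb on chrC and chromosome 10 of loci with equal length and equal counts in both libraries; blue points keep the strand orientation and red points reverse it. The points follow separate straight lines over a 115869-nt stretch of chromosome 10; some loci match a mirrored pair on chrC and appear at both positions.

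Clustering was examined because plant small nucleolar RNA genes, whose RNAs guide modification of ribosomal RNA, are known to lie in arrays. Of the 1349 loci, 414 (30.7%) formed 130 clusters on the same strand, against 9.50 clustered loci on average and 24 at most in random placements. Clusters of 2 loci numbered 68 and clusters of 5 or more 19. Some clusters of 2 are chrC loci or nuclear loci that repeat them. Without the nuclear loci that repeat organelle loci, 376 loci formed 111 clusters. Clustered loci were more often listed in both libraries (355 of 414, 85.7%) than single loci (297 of 935, 31.8%). This contrast is not at equal read number, since 72.7% of clustered loci but 19.5% of single loci had 20 reads or more. Clustered loci held 42.2% of stage 1 reads and 56.8% of stage 2 reads, a ratio that became 0.970 when scaled to the median locus. Single loci were at 0.539 (0.532 to 0.546) under that scaling. All 13 loci of 196 nt are single loci. They took 18.9% of stage 1 and 6.25% of stage 2 reads, so a large part of the shift in shares lies in that set. Among loci with at least 20 reads the median log2 ratio was 0.63 for 301 clustered loci and 0.11 for 182 single loci.

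The largest cluster lay in a region on the minus strand of chromosome 3, from 31172423 to 31182643, where 38 loci of 77 to 182 nt occupied 10221 nt in 3 neighbouring clusters of 6, 23 and 9 loci. All 38 were found in both libraries, with 3698 and 7144 reads and a ratio of 1.32 (1.27 to 1.38) that turned to 0.953 (0.916 to 0.992) when scaled to the median locus. Of these, 26 shared length and both counts with another locus of the region, 19 of them with at least 20 reads. With each such group entered once the ratio was 1.17 (1.11 to 1.25). JNnc_loci0406, JNnc_loci0427 and JNnc_loci0435, chosen after their values were seen, each had 620 and 1467 reads. JNnc_loci0404 lay in the same region with 61 reads in stage 1 and 7 in stage 2. Outside it, the largest clusters were 9 loci on chromosome 7 (2028645 to 2030316), with a ratio of 1.73 (1.39 to 2.16), and 8 on chromosome 2 (26257572 to 26258989), with a ratio of 1.36 that turned to 0.982 under that scaling. The highest ratio among the 19 clusters of 5 or more was 2.87 (2.55 to 3.24), for 6 loci on chromosome 6 (6783228 to 6785013), and the lowest 0.866 (0.768 to 0.977), for 6 loci on chromosome 11 (28281849 to 28283088). Of the 19, 14 had an interval above 1 and 1 below 1, while relative to the median ratio of 1.39 there were 6 above and 6 below. The 3 neighbouring clusters of the chromosome 3 region are among the 14. Each of them holds 1 of the loci with 620 and 1467 reads, so they may not be separate signals.

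**Figure D5:**
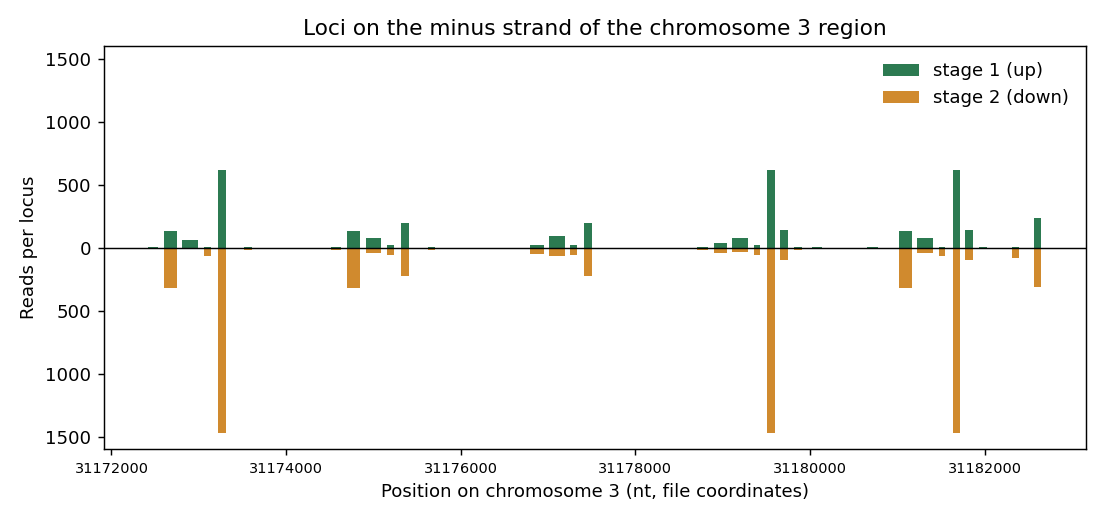
Reads per locus along the minus strand of chromosome 3 between 31172423 and 31182643 (file coordinates in nt), stage 1 upward in green and stage 2 downward in orange; bar width is the locus. The 3 tallest bars are the loci with 620 and 1467 reads.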

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

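Scaling to the median locus was chosen after the data were seen, as were all alternatives for mitochondrial reads, the chromosome 3 region and clustered reads, and those with equal-count groups entered once and without nuclear loci that repeat organelle loci. Clustering of only the loci with at least 20 reads was also added then. Under median scaling the loci at least 2-fold higher in stage 2 went from 159 to 88 and those at least 2-fold lower from 56 to 107, by construction of the scaling. The ratio of the 4 loci JNnc_loci0359, JNnc_loci1184, JNnc_loci1185 and JNnc_loci1239 reversed to 0.884. Under that scaling the ratio also reversed to 0.953 for the chromosome 3 region and 0.970 for clustered loci. The ratio of mitochondrial reads reversed to 1.77 without 5 loci of equal counts, because these hold most of its reads. Keeping entries at or above the median read number left 424 distinct loci in stage 1 and 585 in stage 2, because fewer enter. The other 50 alternative values of the main results stayed on the same side of their threshold or within 1.5 times their count; among these, the 4 other overlap and strand rules for shared loci could not change a number set by common intervals. Among the 75 alternative values for named loci, 59 stayed within their interval, or within 2-fold for a bound, and 12 others moved without changing direction, all under median scaling. The chloroplast difference came nearest to a call, with an adjusted p of 0.0519 without the repeated nuclear loci and 0.0701 for loci of 50 to 500 nt. No paired analysis was possible because each stage has 1 library, and no library could be left out for the same reason. The planned total without rRNA and tRNA loci, the class alternatives by annotated strand and by coverage of a feature, and the host gene lists were not run for lack of an annotation of the files' build. Depth limits the weak loci: a locus with 0 reads could still hold up to 37.2 RPM in stage 1 or 25.5 in stage 2.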

Other observations

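All tests in this part were chosen after the result was seen, except those on stage ratios within clusters and on detection of clustered loci. JNnc_loci0136 on chromosome 1 (37414255 to 37414415), 161 nt long, was 10.2-fold higher in stage 2 (95% interval 7.68 to 13.9), or 7.37-fold scaled to the median locus, on 50 and 747 reads.

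Groups of loci with equal length and exactly equal counts in both libraries numbered 20 and held 57 of the 483 loci of at least 20 reads. Chance coincidence is argued against, since 0 of 100 shuffles of stage 2 counts among loci of similar stage 1 count gave as many, with 20 loci at most. Copies expressed equally and counted separately are also argued against: Poisson counts of equal mean would give 0.111 further members with equal counts, and 37 were seen. Reads that match several copies and were counted at each remain as a candidate explanation, with equal counts at all 3 mirrored pairs of loci on chrC, of at most 3 reads each, and 120 nuclear loci in runs that follow organelle loci, as nuclear copies of organelle segments would. If so, entering each group once would remove 7.54% of stage 1 and 8.68% of stage 2 reads, and the 13 stage 1 only loci of the chromosome 10 stretch may be chloroplast RNA; no sequence was compared.

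Loci listed in 1 library only numbered 697, where binomial sampling of each locus total at equal shares predicts 251.1 (SD 12.2), and 618 without the repeated nuclear loci, against 220 expected. Of the 278 loci with 2 reads in all, 18 were split 1 and 1, where 134 are expected. Stage-specific loci sampled at random could give this pattern, as could repeated reads of few molecules or a rule that called loci within a library. Loci of 1 library with 2 reads (260) and with 3 reads (292) did not differ detectably in number (exact binomial p = 0.187), while those with 4 reads numbered 63, so the explanations cannot be told apart for weak loci. For the 7 such loci with 20 or more reads, sampling predicts 0.000371.

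The 13 loci of 196 nt differed in their stage ratio. Counting error is argued against (Monte Carlo p of homogeneity 0.0001, the smallest that 10000 tables can give). A length bias between the libraries alone would give loci of 1 length a common ratio. Random division among near-identical copies would too, if every read matched all of them. Yet the highest and lowest lay 12-fold apart at the nearest ends of their intervals, which argues against either as the only source of the spread. For the spread, a difference between the tissues and any difference between the 2 libraries in how reads were assigned to the best copy stay open, since each stage has 1 library. The low ratio of the whole set, 0.330, is a separate matter. The other 114 loci of 150 to under 200 nt were at 0.949 (0.928 to 0.971). The 65 loci of 200 nt or longer were at 0.948 (0.913 to 0.985). These values argue against a length bias shared with neighbouring lengths as the only source of 0.330, while a partial one stays open. Loci of 83, 89, 101, 125, 129, 154 and 161 nt were at 2.01, 1.89, 1.34, 0.955, 0.499, 0.556 and 0.968. These are ratios of pooled reads, at lengths picked through the strongest loci. Without the 10 strongest loci of each library they were 1.43, 1.58, 1.52, 0.0904, 0.544, 0.730 and 1.05. The value at 125 nt then rests on 53 and 7 reads. A trend with length was not tested.

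A hypothesis is that the 196-nt loci are genes of a spliceosomal small nuclear RNA. The RefSeq table of assembly ASM3414082v1 lists 71 snRNA genes, 12 of them 197 nt long. Of the 13 loci, 11 could be matched by chromosome to these 12 genes, with 7 loci and 8 genes on chromosome 2 and 4 loci and 3 genes on chromosome 7. Random sets of 13 loci gave 2.65 on average and 9 at most (permutation p = 1e-05, the smallest that 100000 resamples can give). That p is not adjusted for the lengths and offsets tried. The random sets treat loci as independent, so a family of copies gathered on few chromosomes could also score high. The match needs a difference of 1 nt in length. That offset finds little counterpart at other lengths of the most abundant loci: 5 snRNA genes are exactly 161 nt long and 2 exactly 125 nt, while 9 are 1 nt shorter than 161 nt and 1 is 1 nt longer. The opposite offset of -1 matched 6 of the 9 loci of 161 nt by chromosome (permutation p = 0.032, not adjusted for the offsets tried), and 2 snRNA genes are 196 nt and 2 are 195 nt long. At 83, 89, 101, 129 and 154 nt there were 0 within 1 nt. The identity may therefore be wrong, and no sequence was compared.

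A second hypothesis, that loci of a cluster share their stage ratio, was supported weakly. Neighbours in a cluster differed by 1.10 on the log2 scale on average over 194 pairs, against 1.20 when ratios were shuffled among the 283 clustered loci (one-sided permutation p = 0.0291). Another was that clusters hold loci found at both stages at equal read number. Among loci of 3 to 9 reads in all, 31 of 64 clustered loci (48.4%, 35.8 to 61.3) and 71 of 449 single loci (15.8%, 12.6 to 19.5) were in both lists. Some of these loci repeat 1 chloroplast locus, and without organelle loci and the nuclear loci that repeat them the numbers were 19 of 31 (61.3%, 42.2 to 78.2) and 44 of 370 (11.9%, 8.78 to 15.6). Shuffling cluster membership among the latter loci of equal read number gave 10.1 in place of 19 on average (one-sided permutation p = 0.0001, the smallest that 10000 shuffles can give). With exactly 3 reads, the numbers were 12 of 32 and 21 of 293 over all loci. Without the repeated loci they were 2 of 5 and 18 of 253, at the border of the threshold (two-sided Fisher's exact p = 0.0496, one-sided permutation p = 0.0502), and with loci of equal length and counts also entered once they were 2 of 5 and 13 of 103 (Fisher's exact p = 0.141). With that entry alone they were 2 of 6 and 14 of 106 (Fisher's exact p = 0.204), so the difference is not shown at this read number. The comparisons without repeated loci and with exactly 3 reads were chosen after the result was seen. The same outcome would arise if single weak loci are more often products of locus calling, which was not tested, and neighbours in a cluster are not independent.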
